A study of Arabidopsis thaliana with 9 samples.

How the data were processed

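Rosette leaves of Arabidopsis thaliana (Columbia) were profiled by the authors on Affymetrix ATH1 arrays. There were 3 groups of 3 arrays: the inducible DVL4 line with dex (30 µM, read from the written unit um), the same line with mock treatment, and the empty vector line with dex. The labels state 6-leaf plants at 22 °C with 16 h days, harvest 10 h after treatment, and the pooled leaves of 20 plants per replicate. The authors' processing is given as dChip only, and its version, model and any test are not given in the sources used here. Groups and replicate numbers came from the sample titles, and the treatment details from the sample labels and the series text. The replicate numbers were not taken to pair samples.

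The deposited values are intensity on a linear scale, per the labels signal from dChip, for 22810 probe sets in 9 arrays. Array medians ran from 75.4 to 84.1, so no further normalization was applied. All values under the 5th percentile of the pooled values (4.92) were raised to it, and log2 was taken. The 64 AFFX control probe sets were left out of the tests, which left 22746. Low values set the precision of large folds, and between 1091 and 1275 values per array lay under the floor.

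Probe sets were named from the gene table supplied, which lists 14016 of the 22746. Of these 13513 have 1 symbol and 503 several, and the other 8730 are unnamed here. Probe sets listed with several genes were not used in gene-level results. A gene with several probe sets was taken by the brightest one. Short notes on what a gene does come from general knowledge of the genes, not from the data.

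Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with trend=TRUE, all 9 arrays in a single fit, group as the only factor), 2-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Called probe sets passed this threshold, and the first group named in a comparison minus the second gives the sign. Errors on log2 changes are standard errors from limma, and errors on intensities are standard deviations of 3 arrays. Shared changes passed in both comparisons with DVL4 dex and had the same sign. The 2 comparisons share the DVL4 dex arrays. The covariance and sign agreement from that sharing alone came from 100 simulated sets of arrays without effects, with independent noise per probe set. With 3 DVL4 dex arrays, 2 sets of 2 for separate comparisons could not be formed. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

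Named genes followed a rule: in each comparison the 10 largest rises and 10 largest falls among called probe sets with 1 gene, full separation of the arrays and a brighter group above the median of all probe sets. For shared changes the smaller of the 2 changes set the rank. Up to 4 list members with the smallest p were named per list, and further members were named beside them after their values were seen. The text also names all measured reference genes.

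The 26 gene lists held 488 distinct entries, and 6 symbols matched no gene. Only 65 entries had a named probe set, and 5 lists had none. The 7 lists with at least 4 measured members were tested with camera (correlation between genes 0.01), with camera using an estimated correlation, and with fry, adjusted over the 7 lists. No call of camera was made in any comparison, and so none depended on the correlation. Families of at least 8 genes sharing a symbol prefix, and the plastid genes, made 29 sets formed after the annotation was seen.

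The comparisons, lists, naming rule and most alternatives were chosen before the data were examined. These were quantile normalization, median centring, a floor at the 25th percentile or none, leaving out probe sets dimmer than the median, trend=FALSE, robust=TRUE, array weights, fits of only the groups compared, the replicate number as a block, a minimum fold of 1.2 (treat), 2 other definitions of the shared change, and leaving out each array. Settings for the 3 low-5' arrays (dap ratio of 5' to 3' under 0.5) were chosen after seeing the data.

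The steps were tested on simulated data with 22746 genes and independent noise. The 200 genes that changed were all brighter than the median. Far more probe sets were called in the data (5401 against mock), and the adjusted threshold depends on that number. The recovered shares therefore describe the simulated setting only. Against mock, 36.8%, 90.4% and 98.6% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 11 false calls. Against the empty vector the shares were 35.1%, 89.0% and 98.6% with 8 false calls, and for shared changes 26.3%, 86.3% and 98.6% with 1. The comparison of the controls, where no change was simulated, gave 0 false calls. Camera called the 1 simulated list that was shifted, by 1 on the log2 scale, and none of the others. The simulated lists had 20 members, against 4 to 7 measured in the lists tested here, so power for these was not checked.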

Results

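DVL4 belongs to the DEVIL family of small peptides. The Arabidopsis line studied carried a DVL4 transgene inducible by dexamethasone (dex), and its rosette leaves were profiled. Leaves of the DVL4 line harvested 10 h after dex were compared with mock-treated leaves of the same line and with dex-treated leaves of a line carrying the empty vector. Each group had 3 arrays, each from the pooled leaves of 20 plants. No mock-treated empty vector leaves were profiled, so the 2 controls differed in line and in dex at once. The DVL4 transcript and the other DVL/RTFL genes were unnamed on the array here, so whether and how far DVL4 was induced was not measured.

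**Figure D1:**
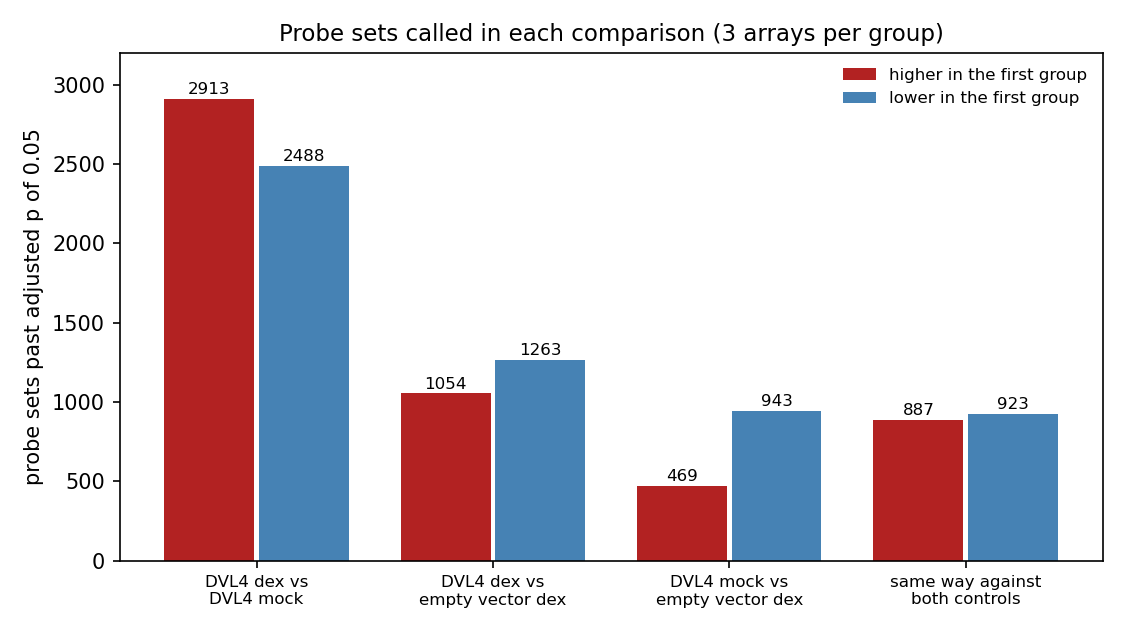
Bars give the number of probe sets past an adjusted p of 0.05 in each comparison, higher (red) or lower (blue) in the first group named, with 3 arrays per group. The dex-treated DVL4 leaves differed from the mock-treated ones in 5401 probe sets, and 1810 changed the same way against both controls.

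Dex in the DVL4 line, against mock, raised BGLU45 most among the named genes. BGLU45, a beta-glucosidase of monolignol glucosides, went from 9.88 ± 0.974 to 1195 ± 176 (mean ± SD, n = 3), a 120-fold rise. AT1G64405 rose 101-fold and the metal transporter gene AT3G58060 (MTP8) 65.2-fold, from 8.19 ± 1.14 to 533 ± 61.9. AT1G15010, AT5G05320, AT4G23680 and AT1G14220 rose 39.7-fold, 35.7-fold, 26.4-fold and 24.3-fold. The sugar transporter gene SAG29 (SWEET15) rose by 4.56 ± 0.26 on the log2 scale (SE), the bZIP factor gene EEL 22.2-fold and the invertase family gene cwINV6 19.6-fold. Raising all values under the 25th percentile (20.1) to it shrank 7 of these 10 folds, to 59.1 for BGLU45, 43.9 for AT1G64405, 26.4 for AT3G58060, 12.7 for EEL, 7.87 for SAG29, 7.24 for AT1G14220 and 6.95 for cwINV6. It left those of AT1G15010, AT5G05320 and AT4G23680 as they were.

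AT5G62210 fell furthest against mock among the named genes, 28.9-fold, to 7.21 ± 5.82. UF3GT and AT4G14090, which encode anthocyanin glycosyltransferases, fell 13.8-fold and 6.13-fold, although the mock arrays varied widely (223 ± 163 and 168 ± 106). AT1G06000, a flavonol rhamnosyltransferase gene, fell 6.24-fold, from 1368 ± 240 to 223 ± 64. The chalcone isomerase-like gene CHIL fell 5.59-fold, and its log2 change was -2.48 ± 0.15 (SE). AT1G64500 fell 6.64-fold, the methionine sulfoxide reductase gene MSRB6 6.33-fold, AT3G44970 6.31-fold, AT2G23910 6.26-fold and AT3G28220 5.65-fold. With the floor at the 25th percentile AT5G62210 fell 10.3-fold and UF3GT 7.66-fold.

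In this comparison limma called 5401 of 22746 probe sets (23.7%), 2913 higher and 2488 lower with dex, of which 725 and 632 changed at least 2-fold. The 3 arrays of one group all lay above the 3 of the other for 43% of probe sets, against 10% by chance. Without DVL4 dex replicate 1 the count was 3477. DVL4 dex replicates 1 and 2 and empty vector replicate 1 had low 5' signal in control probe sets (low-5' arrays), and with that status as a covariate the count was 3996, against 2224 within the high-5' arrays, where DVL4 dex had 1 array.

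Among the 65 genes of the fixed lists that could be measured, 10 rose, 16 fell and 39 did not pass against mock. The auxin response genes IAA29 and WES1 (GH3.5, which conjugates auxin) rose, IAA29 by 4.12 ± 0.43 on the log2 scale and WES1 4-fold, from 40.1 ± 3.24 to 161 ± 12.2 (SD), while HAT2, GH3.1 and GH3.3 did not pass (0.22, 0.49 and 0.09). Both measured cytokinin response genes, the type-A regulators ARR15 and RR16, fell by 2.37 ± 0.29 and 0.81 ± 0.15. The clock gene GI rose 12-fold, from 39.5 ± 9.72 to 477 ± 135, but whether the groups were harvested at the same time of day was not stated in the sources used here. In the cell cycle list, SIM, an inhibitor of cyclin-dependent kinases in endoreduplicating cells, rose 2.25-fold. PRL, which encodes the replication licensing factor MCM7, fell by 1.07 ± 0.21, and AUR1 and AUR2 did not pass (-0.34 and -0.04).

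Cell wall genes split. Of 7 measured expansins and xyloglucan endotransglucosylases, XTH19 rose 9.82-fold, XTH16 and EXPA15 fell by 1.18 ± 0.19 and 0.56 ± 0.11, and EXPA8, XTH33, XTH18 and EXPA4 did not pass (-0.59, -0.44, 0.66 and -0.04). Among 5 leaf shape, polarity and boundary regulators, YAB3 fell by 0.55 ± 0.13 and AN rose by 0.44 ± 0.12, while YAB5, PHV and JAG did not pass (0.07, 0.03 and 0.08). In the list of epidermis, trichome and guard cell markers, TRY, a repressor of trichome fate, fell by 1.21 ± 0.12, and FMA (FAMA), MUTE and SPCH did not pass (-0.53, 0.36 and 0.03). All 3 measured flavonoid and anthocyanin genes fell, with DFR at -3.10 ± 0.85 beside UF3GT and AT4G14090.

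In the stress and defence lists single genes passed against mock. CML38 and STZ of the touch, wounding and early stress list fell by 1.28 ± 0.25 and 1.12 ± 0.27, while WRKY53 and WRKY22 did not pass (0.94 and -0.35). AER fell by 1.27 ± 0.11, and 4 other detoxification genes did not pass, with GSTU20 at -0.20, UGT73B4 at 0.64 and GSTU25 at -0.09. Fes1A of the heat shock list fell by 0.58 ± 0.12, COR15A of the abscisic acid and drought list by 0.38 ± 0.10 and UGT74B1 of the glucosinolate and camalexin list by 0.38 ± 0.09, with ATHSP22.0, COR47 and BCAT4 not past (0.12, 0.23 and -0.12). SAG101 of the salicylic acid and PR defence list rose by 0.62 ± 0.19, and GRX480 did not pass (0.35). In the senescence list SAG29 rose and WRKY6 did not pass (0.65 ± 0.21, limma adjusted p = 0.0509). EXPA7 among the root markers rose by 1.03 ± 0.30, and EXPA18 and PYK10 did not pass (0.18 and -0.39). Of the 2 reference genes measured, PEX4 rose 1.42-fold and AT4G34270 (TIP41) stayed at 0.10 ± 0.09.

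No measured gene passed against mock in 4 lists. These were ethylene (EIN3 0.23, PDF1.2b -1.08, PDF1.2 -1.31), gibberellin (GID1A -0.46, GID1C 0.34, GID1B -0.15), photosynthesis (PRK -0.17, LHCB4.1 -0.06, RCA -0.03) and phenylpropanoid and lignin synthesis (HCT -0.05). Adjusted over the list alone, EIN3, PDF1.2, GSTU20, UGT73B4, WRKY6 and FMA also passed, and the other lists had the same counts. The jasmonate, brassinosteroid, flower and pollen, and vascular lists had no named member here, like the DVL/RTFL list.

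As sets, 0 of the 7 lists with at least 4 measured members passed limma's camera test against mock. The auxin list was the only one under an unadjusted p of 0.05 (adjusted p = 0.0927, and 0.382 with an estimated correlation). The fry test, which asks whether the members changed at all rather than more than other genes, called 5 lists. Auxin was higher, and expansins and xyloglucan endotransglucosylases, touch, detoxification and epidermis were lower. The expansin list had a median change of -0.44 but a mean of 0.16. SAG101, EXPA7, DFR, COR15A, AN and UGT74B1 lost their calls in 6 to 9 of up to 20 other settings each, and STZ in 4.

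Against the empty vector leaves, both treated with dex, XTH19 rose most among the named genes. This xyloglucan endotransglucosylase gene rose 9.51-fold, to 457 ± 96.7 (mean ± SD, n = 3). AT4G12490 rose 9.48-fold and AT1G75990, a gene for a proteasome lid subunit, 8.16-fold, from 124 ± 19.7 to 1002 ± 88.5. AT5G60140 and AT1G15010 rose 7.83-fold and 7.31-fold, EEL 7.04-fold, BGLU45 6.9-fold and AT3G58060 5.79-fold. AT4G14695 and AT2G24550 rose 4.33-fold and 4.24-fold. With the floor at the 25th percentile AT5G60140 rose 4.43-fold only.

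The largest named fall against the empty vector was in AT3G28220, 7.05-fold, from 1072 ± 259 to 149 ± 12.8. AT5G58160 fell 6.67-fold, AT1G19960 5.76-fold, AT1G52000 5.33-fold and AT5G55450 5.22-fold. AT5G03350 fell 4.87-fold, AT3G48080 4.67-fold, AT1G11330 4.6-fold, AT1G13470 4.25-fold and AT3G28270 4.04-fold. AT5G03350 lost its call in 5 of up to 20 other settings and AT1G13470 in 4. With the floor at the 25th percentile AT5G58160 fell 4.04-fold. AT1G06000 fell 3.61-fold here and CHIL by 1.47 ± 0.15, while UF3GT, AT4G14090 and DFR did not pass (-0.81, -0.53 and 0.04).

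Here limma called 2317 probe sets (10.2%), 1054 higher and 1263 lower in DVL4 dex, with 237 and 312 at least 2-fold. Arrays of the 2 groups separated fully for 24.8% of probe sets, against 10% by chance. With each array centred on its median the split turned to 1476 higher and 1080 lower. The count fell to 993 without DVL4 dex replicate 1 and to 1323 without replicate 2. With the low-5' covariate it was 2471, within the high-5' arrays 398 and within the low-5' arrays 937, while leaving out the 3 low-5' arrays, which left 1 DVL4 dex array, gave 4.

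Fewer of the 65 list genes passed against the empty vector, 5 higher and 6 lower. WES1 rose 3.07-fold, while IAA29, with a rise of similar sign against mock, did not pass (1.46 ± 0.43, limma adjusted p = 0.0624). GI rose 2.82-fold and SAG29 3.63-fold. SIM rose by 0.83 ± 0.14 and PRL fell by 1.33 ± 0.21. XTH19 rose, EXPA15 fell by 0.41 ± 0.11, and XTH16 did not pass (-0.08). TRY fell by 1.08 ± 0.12, AER by 0.89 ± 0.11, COR15A by 0.64 ± 0.10 and Fes1A by 0.55 ± 0.12. EXPA15 lost its call in 14 of up to 20 other settings and Fes1A in 5.

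Several genes that passed against mock did not pass against the empty vector. ARR15 and RR16 were among them (-0.74 and 0.19), as were YAB3 and AN (0.04 and 0.22), CML38 and STZ (-0.58 and -0.91), SAG101 (0.07), UGT74B1 (-0.03), EXPA7 (0.28) and PEX4 (0.19). All measured genes of the ethylene, gibberellin, photosynthesis and lignin lists stayed below the threshold, with GID1B at -0.60, RCA at -0.10 and HCT at 0.03. Adjusted over the list alone, IAA29, COR47, STZ and UGT73B4 also passed. Camera called 0 of 7 lists, with touch and auxin under an unadjusted p of 0.05 (adjusted p = 0.0967 and 0.115, and 0.318 for the smallest with an estimated correlation). Fry called 3, with auxin higher and touch and epidermis lower. The expansin list again had a median below 0 (-0.08) and a mean above it (0.31), and the epidermis list, lower by fry, had a median of 0.01 and a mean of 0.03.

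Most of the genes called against the empty vector had also changed against mock, and in the same direction. XTH19 and AT1G75990 rose by similar folds against both controls, 9.82-fold and 8.62-fold against mock beside 9.51-fold and 8.16-fold, with control differences of -0.05 ± 0.48 and -0.08 ± 0.13 on the log2 scale, that of XTH19 too imprecise to call its controls level. TBL26 and AT3G28270 fell by similar folds too, 3.31-fold and 3.77-fold against mock beside 3.37-fold and 4.04-fold. AT1G15010, EEL, BGLU45, AT3G58060, AT2G24550 and cwINV6 rose more against mock than against the empty vector, and their control difference passed. With the floor at the 25th percentile that difference no longer passed for EEL and cwINV6. It did not pass for AT5G60140 and AT4G14695 (-1.17 and -0.95), and with that floor AT5G60140 rose 4.43-fold against each control. BGLU45 stood at 9.88 in mock, 175 in empty vector and 1195 in DVL4 dex leaves. Of the shared falls, IAGLU, which encodes an auxin glucosyltransferase, dropped from 420 ± 32.2 and 311 ± 72.2 in the controls to 102 ± 19.2. AT3G28220, AT1G65870, AT1G06000, MSRB6, AT2G15020, AT5G55450 and AT5G02890 fell at least 2.86-fold against each control. Against the empty vector AT2G15020 lost its call in 5 of up to 20 other settings and cwINV6 in 4, and without the low-5' arrays cwINV6 rose by 0.85 only.

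**Figure D2:**
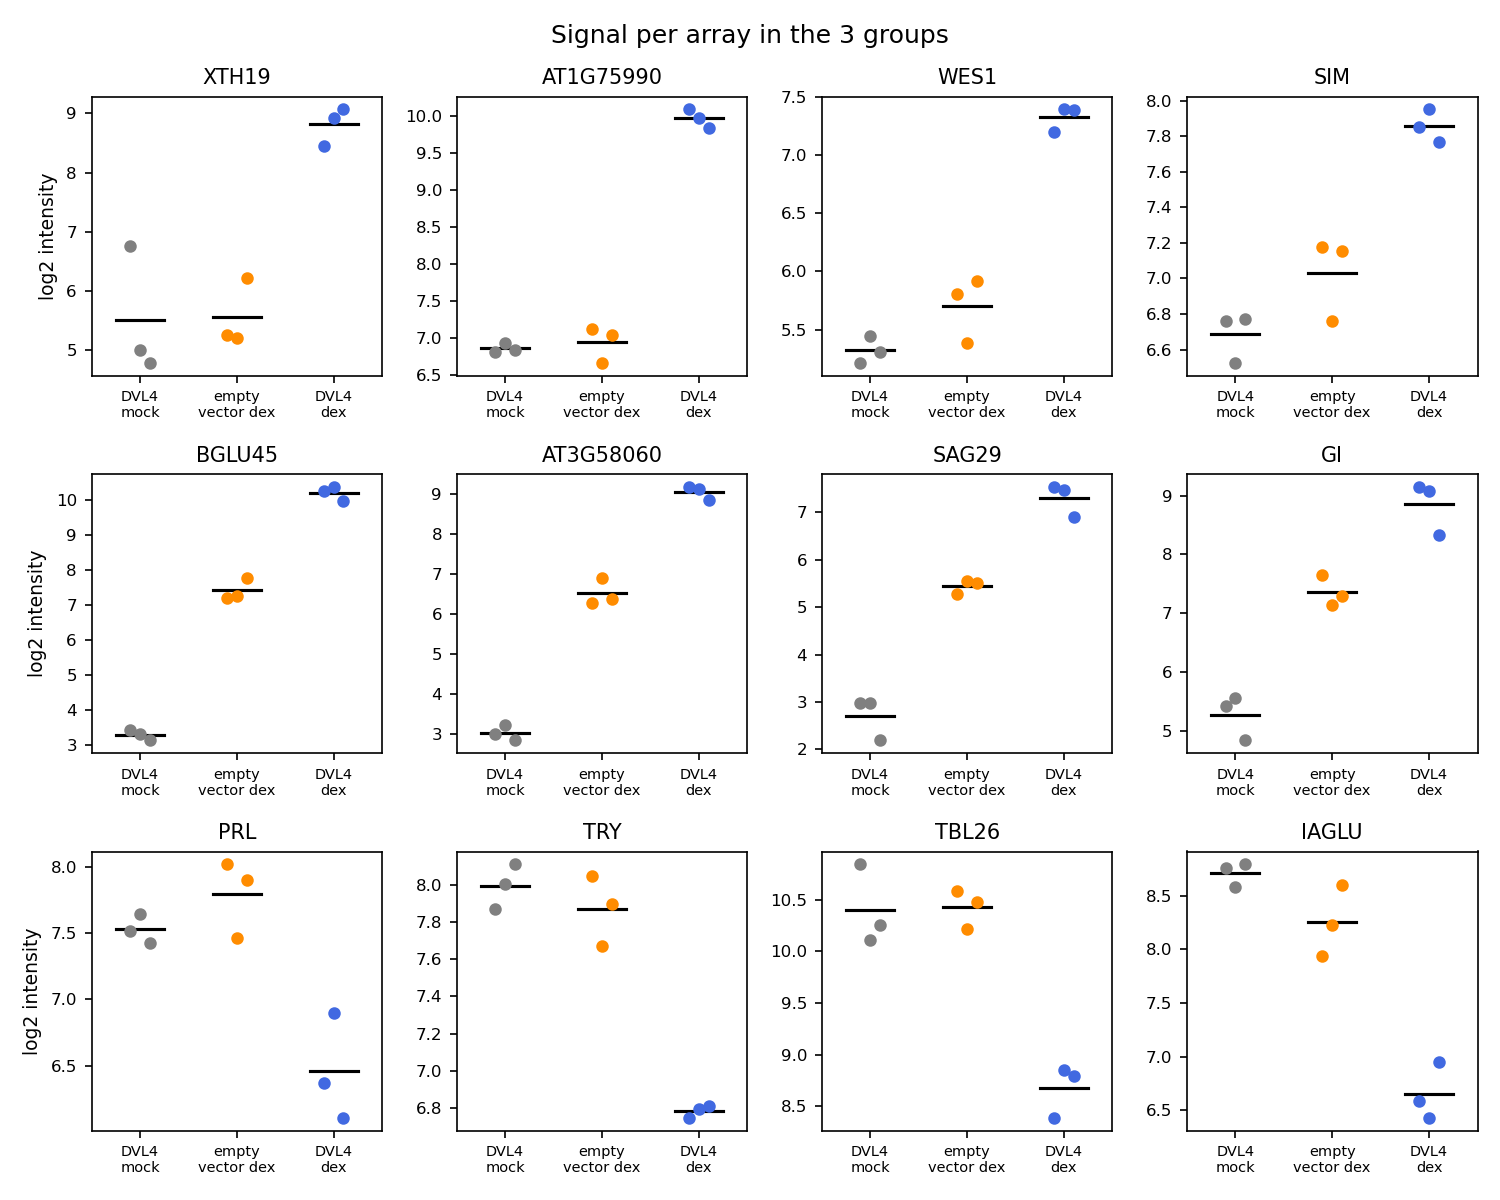
Points give the log2 intensity of each array before any floor, and bars the mean of the 3 arrays per group, for 12 genes changed the same way against both controls. AT1G75990 and TBL26 were level in the 2 controls (log2 differences of -0.08 and -0.02), the mock arrays varied widely for XTH19 (55.9 ± 45.1), and BGLU45, AT3G58060, SAG29 and GI were higher in empty vector dex than in DVL4 mock leaves.

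From the fixed lists, 11 genes changed the same way against both controls. WES1, SIM, GI, XTH19 and SAG29 rose, and PRL, EXPA15, TRY, AER, COR15A and Fes1A fell. Of these, GI and SAG29 also differed between the controls, by -2.09 ± 0.26 and -2.70 ± 0.26 in mock relative to empty vector leaves. WES1, SIM, PRL and TRY did not pass between the controls (-0.38, -0.34, -0.26 and 0.12). In DVL4 dex replicate 3 alone, against the high-5' controls, WES1 was higher by 2.06 and 1.73 and SIM by 1.08 and 0.81. PRL was lower at -1.42 and -1.57, and TRY at -1.18 and -0.97. These arrays had also entered the calls, so the values are no separate check.

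In all, 1810 probe sets passed in both comparisons with the same sign, 887 higher and 923 lower, and 11 passed with opposite signs. Lists drawn independently would share 135 higher and 138 lower. The shared calls made up 33.5% of the calls against mock and 78.1% of those against the empty vector, and 181 higher and 153 lower changed at least 2-fold in both. Both comparisons used the same DVL4 dex arrays, and part of the excess may come from them. Simulated arrays without effects gave 0 shared calls and a covariance of the 2 changes of 0.0339, against 0.18 observed. The 2 changes had the same sign in 66.7% of simulated probe sets, against 76.0% observed. With no effects simulated, 0 shared calls follow from the adjustment. They do not measure how much overlap the common arrays gave. The simulated arrays also left out the low 5' signal, which was unequal between the groups. With each array centred on its median, 1198 were higher and 794 lower.

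The shared count leaned most on DVL4 dex replicates 1 and 2, both low-5' arrays. It was 758 without DVL4 dex replicate 1, 1005 without replicate 2 and 1870 without replicate 3, the high-5' one. With the low-5' covariate it was 1737, and 1459 of the 1810 (80.6%) kept both calls. Leaving out the 3 low-5' arrays left 4 shared calls, with 1 array of DVL4 dex. Of 937 probe sets called against empty vector within the low-5' arrays, 885 (94.5%) had the same sign within the high-5' arrays, with a median change of 0.60 in the called direction beside 0.98.

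The 2 controls differed most in AT1G64405 among the named genes. It was 40.6-fold lower in DVL4 mock than in empty vector dex leaves, at 8.84 ± 1.85 against 353 ± 7.11 (mean ± SD, n = 3). BGLU45 was 17.5-fold lower, AT5G51950 16.8-fold, AT5G05320 13.8-fold, AT1G14220 13.7-fold and AT4G23680 13.1-fold. AT3G58060, AT1G10585, AT1G49500 and AT5G15140 were 11.3-fold, 8.9-fold, 7.37-fold and 7.01-fold lower. With the floor at the 25th percentile AT1G64405 differed by -4.14 on the log2 scale, and BGLU45 was 8.57-fold, AT1G10585 5.65-fold, AT5G51950 5.59-fold, AT3G58060 4.56-fold and AT5G15140 3.92-fold lower. AT1G14220, then 4.09-fold lower, lost its call.

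Higher in mock was first AT4G12490, 15.5-fold, at 294 ± 147 against 17.8 ± 3.6. AT5G62210 was 10.4-fold higher, AT5G61590 (DEWAX, an ERF factor) 5.69-fold, AT1G66760 5.54-fold, AT4G37240 5.25-fold and AT3G44970 4.59-fold. EXO, a gene induced by brassinosteroids, was 3.79-fold higher, AT3G19680 3.33-fold, ARR15 3.09-fold and AT5G48490 2.93-fold. AT4G12490 stood lowest in empty vector leaves, and it did not rise against mock in the dex-treated DVL4 line.

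Between the controls 4 list genes were higher in mock and 5 lower, of 65. ARR15 and RR16 were higher by 1.63 ± 0.29 and 1.01 ± 0.15, XTH16 by 1.10 ± 0.19 and YAB3 by 0.59 ± 0.13. IAA29 was lower in mock at -2.66 ± 0.43, GI at -2.09 ± 0.26, SAG29 at -2.70 ± 0.26, WRKY6 at -1.12 ± 0.21 and WRKY53 at -2.36 ± 0.55. UF3GT, DFR and AT4G14090 were higher in mock by 2.98 ± 0.80, 3.13 ± 0.85 and 2.08 ± 0.59 but did not pass (limma adjusted p = 0.0582, 0.0615 and 0.0689). Adjusted over the list alone these 3, SAG101, CML38, AER, UGT74B1 and PEX4 also passed. WRKY53 and YAB3 lost their calls in 9 and 10 of up to 20 other settings. Camera and fry called 0 of 7 lists, 0 had an unadjusted camera p under 0.05, and the smallest adjusted p was 0.221 (0.406 with an estimated correlation). The touch list had a median of 0.14 and a mean of -0.34.

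Between the controls limma called 1412 probe sets (6.21%), 469 higher and 943 lower in mock, with 117 and 336 at least 2-fold. Groups separated fully for 26.2% of probe sets, against 10% by chance. Median centring gave 714 higher and 904 lower, and quantile normalization 674 and 866. The count was 747, 580 and 480 without DVL4 mock replicate 1, 2 or 3, 615 without empty vector replicate 3, and 1505 with the low-5' covariate. Of the 943 probe sets higher in empty vector dex than in DVL4 mock, 253 were higher again in DVL4 dex than in empty vector and 169 lower. Line and dex changed together in this comparison, so neither was separated.

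Control probe sets marked 3 arrays as low in 5' signal. The ratio of 5' to 3' signal of the dap spike-in was 0.228 in empty vector replicate 1, 0.278 in DVL4 dex replicate 1 and 0.262 in DVL4 dex replicate 2, and at least 0.601 in the other 6 arrays. Actin gave 0.279, 0.33 and 0.226 in these 3 arrays and at least 0.422 in the others. Signal at the 3' end of actin had means of 3057 ± 157 in DVL4 dex, 2490 ± 122 in DVL4 mock and 2755 ± 72.5 in empty vector dex (n = 3). Of all probe sets, 428 passed for the low-5' status itself.

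**Figure D3:**
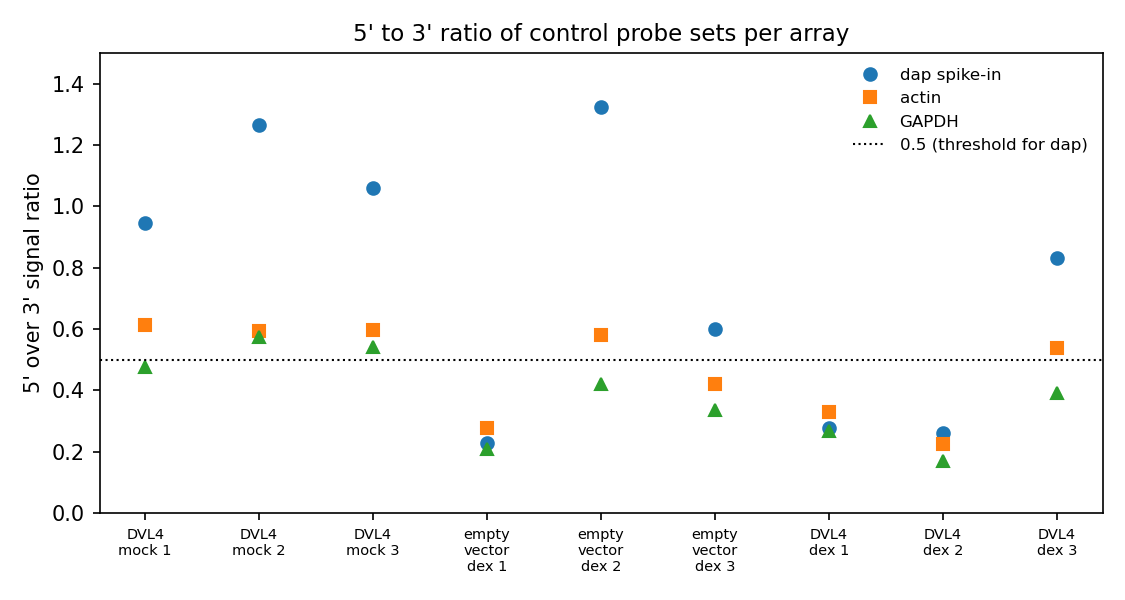
Points give the ratio of 5' to 3' signal of the dap spike-in, actin and GAPDH probe sets on each of the 9 arrays, and the dotted line the 0.5 threshold used for dap. Empty vector replicate 1 and DVL4 dex replicates 1 and 2 had dap ratios of 0.228, 0.278 and 0.262, and no mock array was below the line for dap.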

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

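The settings for the low-5' arrays were chosen after seeing the data, and the others before. Genes were followed in 20 settings, without array weights, treat or the fits within high-5' or low-5' arrays, and 159 of 286 gene values were in the one without dim probe sets. Of the 286, 125 were called, 0 of them reversed, 50 kept the call wherever it was run and 75 lost it in at least 1 setting, of which 65 did so when the low-5' arrays were left out. Both scalings, both other floors, the filter on dim probe sets, robust=TRUE and the low-5' covariate kept all 4 counts within 1.5 times. Floors change folds where 1 group lies near background. Array weights (0.459 to 2.69) gave 8999 calls against mock, 2218 between the controls and 2780 shared, of which 5389, 1381 and 1761 were among those without weights. With treat at 1.2-fold the counts were 2166 against mock, 634 against empty vector, 359 between controls and 459 shared. Fitting only the groups compared gave 1164 against empty vector, 892 between controls and 945 shared. With trend=FALSE 813 passed between controls. Leaving out the 3 low-5' arrays gave 1360, 4 and 614 in the 3 comparisons and 4 shared. Within the high-5' arrays 2224 passed against mock and 398 against empty vector, and within the low-5' arrays 937 against empty vector. Against the mean of the controls 4682 passed, and 972 shared calls were at least 1.5-fold in both. Fry called 5 and 3 lists against mock and empty vector, where camera called 0. Leaving out 1 array gave 3477 to 6104 against mock, 993 to 2259 against empty vector, 480 to 2093 between controls and 758 to 1870 shared, with 0 to 1, 0 to 1 and 0 to 0 lists in the 3 comparisons. Where groups kept 1 low-5' or high-5' array it was assumed to vary like the others. For array weights, trend=FALSE and the single arrays the cause was not tested.

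The replicate number as a block gave 5116, 2057, 1256 and 1636 calls, and 0 lists. Arrays sharing a number correlated at -0.15 to 0.14 after group means were removed, and 3 of 9 arrays correlated best with their own number, so nothing was paired.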

Other observations

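The families here were formed after the annotation was seen. The tests of low 5' signal and of a graded pattern were chosen only after their results were seen. The splits were set before, as was the share of shared calls picked by their control difference, given in the last paragraph. That share also counts controls that differed the opposite way, so it is not a share of genes alike in the controls. Of 8 measured ATG genes, ATG8H, ATG8E, ATG8F and ATG8C rose in DVL4 dex leaves against mock, by 1.12 ± 0.12, 0.66 ± 0.12, 0.64 ± 0.08 and 0.34 ± 0.08 on the log2 scale (SE, n = 3). ATG8H, ATG8E and ATG8F also rose against the empty vector, by 0.78 ± 0.12, 0.76 ± 0.12 and 0.35 ± 0.08, and 0 differed between the controls. The ATG family passed limma's camera test against both controls (adjusted p = 0.00358 and 0.00128 over 29 families). With an estimated correlation adjusted p = 0.866 and 0.920, so neither call held.

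Plastid-encoded genes showed a shift that followed the low-5' arrays. Of 69, 11 were lower in DVL4 dex than in mock leaves (median -0.39, camera adjusted p = 0.000398, and 0.866 with an estimated correlation). Between the controls 5 were higher in mock (median 0.27, adjusted p = 0.00204, and 0.983 with an estimated correlation), and against the empty vector 1 was lower (median -0.14, adjusted p = 0.22). With the low-5' covariate the medians were 0.04, -0.02 and 0.06, with adjusted p = 0.885, 0.533 and 0.428.

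Splits of 6 arrays into 3 and 3 are too few (10) for a share under 0.05. The real split gave 5401, 2317 and 1412 calls, and the highest other 0, 236 and 0, each real split standing first as 1 of 10. The 236 came from grouping the 3 low-5' arrays. Of 100 partitions of all 9 arrays only the real one, 1 of 100, gave 1810 shared calls or more, and the next highest, with the low-5' arrays as a group, gave 108.

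Low 5' signal may add to the shared changes, and how much it adds was not settled. With the covariate 80.6% of shared calls remained. Of 937 probe sets called against the empty vector between the low-5' arrays, 94.5% had the same sign between the high-5' arrays, none of which chose them. Each of these 2 contrasts compared arrays of like 5' status. Their agreement therefore shows a difference from the empty vector in both kinds of array. It does not show how many shared calls came from low 5' signal, and it leaves out the comparison with mock. The low-5' arrays were 2 of 3 in DVL4 dex and none in DVL4 mock, so the covariate cannot separate all of it.

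Among the shared calls, 340 probe sets also differed between the controls in the same order, 253 rising and 87 falling from DVL4 mock over empty vector dex to DVL4 dex. This could suggest a graded response to dex or to the activator carried by both lines, or a difference in dose between lines. The covariance of the 2 steps was -0.0136, above the highest of 100 simulations without effects (-0.0318). Without the low-5' arrays it was -0.063, below the highest simulated value of -0.0482 and the simulated mean of -0.051, so the test cannot tell. The simulations took the spread of all groups together. From the spread of the empty vector arrays alone, -0.052 would arise with all arrays and -0.0619 without the low-5' ones. The simulated values are therefore no exact reference. Corrected for the shared empty vector arrays, the covariance was 0.0384 with all arrays and -0.00118 without the low-5' ones. Low-5' arrays grew in number from DVL4 mock over empty vector dex to DVL4 dex, which can raise the covariance by itself. Of the 340 themselves, 86.8% kept all calls with the covariate. Without the low-5' arrays their median steps were 0.76 and 0.64 in the called direction, beside 0.76 and 0.75 with all arrays. Since the same arrays had chosen them, low 5' signal was not excluded as a source.

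A response to DVL4 alone would leave the 2 controls alike, if DVL4 was off in mock leaves and the lines did not differ otherwise. TBL26 and AT1G75990 had level controls. The DVL4 transcript was not measured, so a response to DVL4 alone was not shown for them. Of the shared calls, 199 (11%) had a control difference whose 95% interval excluded 25% of the change against mock, in its direction. They were 67 higher and 132 lower. Controls that differed the opposite way counted too, as for AT5G55450, at -0.80 in mock relative to empty vector leaves. The 199 were therefore not all alike in the controls. The 11% lay between the under 5% set for a graded response and the at least 20% set against it, so the test cannot tell which may hold. Imprecise control differences also kept probe sets out of the share, as for XTH19 (-0.05 ± 0.48). Leaves of an empty vector line with mock treatment could separate line from dex in the controls. They would not separate DVL4 from a difference in dose between the lines.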
